A study of Mus musculus with 16 samples.

How the data were processed

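The samples were 16 libraries of mouse 8-cell embryos, 4 in each of 4 groups injected at the zygote stage with dsRNA against GFP, Tfap2c, Tead4 or both. Per the labels' protocols, zonae were removed with acidic Tyrode's solution, embryos were cultured in KSOM medium, and pools of 10 embryos (about 80 cells) were taken. Polyadenylated RNA was reverse transcribed with SuperScript II and amplified by a Smart-seq2 procedure, and libraries were made with a TruePrep V2 kit, per the same protocols. CASAVA, Trim Galore, STAR and Cufflinks and the mm10 genome are named in the submitters' processing notes. Which step each tool served, their versions and the gene annotation are not given in the sources used here. The deposited values are FPKM per gene, scaled to library size and gene length by the authors before deposit. No deposited value was on a log2 scale, and all log2 values were computed here.

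The table had 43496 lines, of which 59 repeated an identifier, which left 43437 genes. In all, 27 gene names had been turned into dates by a spreadsheet and were restored from their identifiers. Gene symbols were found for 32973 identifiers, and 123 symbols were shared by several identifiers. The table held 0 columns of samples from outside the series. Locations are those of GRCm38.p6, the assembly known as mm10.

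Read counts and library totals were not used here, so the absolute depth is unknown. Relative depth was estimated from the spacing of low FPKM values of single genes, which move in steps of 1 fragment. It ran from 0.873 to 1.12 of the mean of the 16 libraries, and from 53.9% to 63% of the ratios lay at whole steps, so it is approximate. No confidence interval from counts can be given, and precision rests on the spread between libraries. FPKM sums ran from 799260 to 874436, the 10 most abundant genes took from 12.2% to 17.8% of a library, and mitochondrially encoded genes from 7.06% to 12.1%.

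Groups, the tests of genes and lists, the gene lists and the alternatives were chosen before the data were examined. Splits of the libraries and most tests of explanations were added later. Genes with at least 1 FPKM in at least 4 of the 16 libraries were kept, 11422 in all. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on expression). The fit held all 16 libraries, with a term for group and a term for cross. Contrasts were each knockdown against the GFP control, the double against each single knockdown, and the non-additive part, which is the double minus both single changes. A change passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and adjusted p values of genes are from limma throughout. Tests were two-sided. A second fit with a group by cross interaction tested whether a change differed between crosses. Tfap2c and Tead4 were also tested by exact permutation of 4 against 4 libraries, for which the smallest possible p is 0.0286. Library measures were compared between groups and between crosses by exact permutation as well.

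In all, 27 gene lists were set: cell polarity, apical cortex and microvilli, actin regulators, tight and adherens junctions, keratins and desmosomes, trophectoderm, pluripotency, primitive endoderm, Hippo pathway, YAP-TEAD targets, AP-2 and TEAD families, oocyte transcripts, 2-cell transcripts, interferon and dsRNA response, p53 and stress, cumulus markers, sperm markers, blood markers, mitochondrial transcripts, ribosomal proteins, oxidative phosphorylation, proteasome, G2/M, glycolysis, sterol synthesis, endocytosis and lysosome, and 1 more whose result is not reported here, as for some single genes. The 23 lists with at least 5 measured genes were tested with camera from limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. camera compares a list with the other genes, so its direction can differ from the sign of the list's own median. Adjustment was over the 23 lists of a comparison. Lists can share genes, and 4 of the 10 measured YAP-TEAD targets and 6 of the 23 Hippo genes are in another list too.

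Genes were named by a rule. Tfap2c and Tead4 were named in each comparison, and so were the 5 largest rises and falls against the control that passed, had a mean of at least 5 FPKM in 1 of the groups and moved the same way in both crosses. Each list gave up to 3 members by lowest p. The genes Cdx2, Gata3, Pard6b, Ezr, Rhoa, Pou5f1, Nanog, Sox2, Yap1 and Tfap2a were always looked up. Contrasts between knockdowns and the non-additive part gave the 3 largest rises and falls each. From these candidates the text names those whose symbols a reader can place, and a few others are said to be chosen after their values were seen.

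The fit was tested on simulated data made from the 16 libraries with 200 of 11422 genes changed. These were drawn from genes with a mean log2(FPKM + 1) above 2. Where more genes change, the adjusted p threshold is less strict, so recovery among real changes may differ. At log2 changes of 0.5, 1 and 2, the fit recovered 29.9%, 94% and 98.5% for the Tfap2c knockdown, 43.3%, 86.6% and 100% for the Tead4 knockdown and 34.3%, 80.6% and 97% for the double knockdown. It recovered 34.3%, 79.1% and 97% for the double against the Tfap2c knockdown, 38.8%, 89.6% and 97% for the double against the Tead4 knockdown, and 16.4%, 62.7% and 87.9% for the non-additive part. With no gene changed, 0 genes passed in each of these. A simulated list of 20 genes moved by 0.5 was called in each of the 5 comparisons tested for lists, and 1 list with no change was called in the Tead4 simulation. Simulated genes varied independently, whereas members of real lists correlate, at an estimated 0.475 for ribosomal proteins. The simulation therefore does not tell how often real lists pass by error.

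Comparisons against the GFP control share its libraries. Their correlation, covariance and overlap were set beside 100 simulated draws of unchanged groups against the same controls, and the correlation was recomputed with the controls divided between the comparisons. Library labels such as A1 recur in each group, and whether they pair libraries was checked by correlating residuals. Alternatives tried were pseudocounts of 0.1 and 5, no expression filter, a filter of 5 FPKM, median-ratio rescaling, quantile normalization, no cross covariate, each cross alone, a replicate block, array weights, a fit of only the groups compared, an estimated correlation for lists, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Isoforms, splicing and sequence variants were left out because the values are sums per gene.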

Results

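Polyadenylated RNA was measured in 16 libraries from mouse embryos at the 8-cell stage. Each library was made from 10 embryos, or about 80 cells. Zygotes had received double-stranded RNA (dsRNA), which depletes the matching transcript, against GFP as the control, against Tfap2c, against Tead4, or against both. Each of these 4 groups held 4 libraries, named A1, A2, B1 and B2 after the cross of the embryos. Mothers were C57BL/6J×CBA/J hybrids in cross A and C57BL/6J×DBA/2J hybrids in cross B. The values are FPKM (fragments counted per gene, scaled to transcript length and library size), and 11422 genes with at least 1 FPKM in at least 4 libraries were tested. Values are given as mean ± SD (n = 4 libraries), and changes are differences of log2(FPKM + 1) from limma. The labels do not state that libraries of a group came from separate cultures or matings, so p values measure the spread between these pools of embryos. Read counts per library were not used here, so the absolute depth behind each value is unknown. From 10049 to 10504 genes reached 1 FPKM in a library.

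Tfap2c, on chromosome 2 at 172545678 to 172558622 of mm10 (ENSMUSG00000028640), encodes an AP-2 transcription factor. Tead4, on chromosome 6 at 128227143 to 128300813 (ENSMUSG00000030353), encodes a TEAD transcription factor that works with YAP. Tfap2c mRNA stood at 43.2, 38.8, 28.3 and 32.4 FPKM in GFP A1, A2, B1 and B2. It stood at 13.9, 15.4, 16.1 and 17.8 FPKM in the Tfap2c knockdown and at 16.4, 16.1, 16.4 and 15.7 FPKM in the double knockdown, in the same order. The mean was 15.8 ± 1.65 FPKM in the Tfap2c knockdown and 16.2 ± 0.342 FPKM in the double knockdown, against 35.7 ± 6.6 FPKM in the control. These means were 44.3% and 45.3% of the control, with log2 changes of -1.11 (adjusted p = 8.62e-06) and -1.08 (adjusted p = 1.46e-05). Tead4 mRNA stood at 58.4, 46.5, 47.7 and 41.8 FPKM in the control libraries, a mean of 48.6 ± 7 FPKM. It stood at 8.05, 5.57, 5.99 and 11 FPKM in the Tead4 knockdown and at 8.17, 5.40, 9.62 and 14.8 FPKM in the double knockdown. The means of 7.66 ± 2.49 and 9.49 ± 3.94 FPKM were 15.7% and 19.5% of the control, with log2 changes of -2.55 (adjusted p = 2.22e-05) and -2.31 (adjusted p = 1.15e-05). The exact two-sided permutation p was 0.0286 for each of these 4 comparisons, the smallest that 4 against 4 libraries can give. Each library of both crosses carried the depletion named on its label.

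Each target was also read in the embryos injected against the other gene. Tead4 mRNA was at 58.2% of the control in the Tfap2c knockdown, with 19, 25.9, 37.4 and 30.8 FPKM in A1, A2, B1 and B2 (28.3 ± 7.77 FPKM). Its log2 change was -0.79 (adjusted p = 0.0192, exact permutation p = 0.0286). That call was lost without GFP A1 (adjusted p = 0.0692), GFP A2 (0.0507) or Tfap2c knockdown A1 (0.0594). Tfap2c mRNA in the Tead4 knockdown was 34.8 ± 1.67 FPKM, 97.4% of the control (adjusted p = 0.953, exact permutation p = 0.914).

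**Figure D1:**
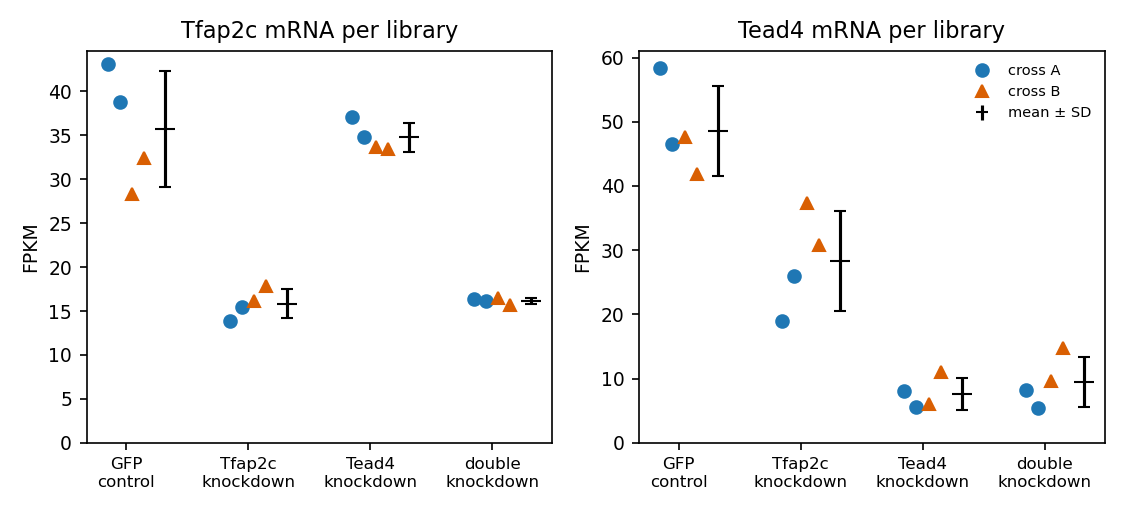
FPKM of Tfap2c and Tead4 in each of the 16 libraries by group, with cross A as circles, cross B as triangles and bars for mean ± SD. Tfap2c lies between 13.9 and 17.8 FPKM in every library injected against it, and Tead4 between 5.40 and 14.8 FPKM in every library injected against it.

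The 16 libraries separated by Tfap2c dsRNA and by cross. Across genes, Pearson correlations of log2 values lay between 0.919 and 0.976 over all pairs and between 0.962 and 0.976 for the 2 libraries of a group and cross. The first principal component held 28.2% of the variance and set libraries with Tfap2c dsRNA apart from those without. Double knockdown B2 was the nearest of these to the control libraries. The second component, with 15.7%, set cross A apart from cross B. The labels used give no batch, so here and below cross may stand for batch as well. The share of FPKM on mitochondrial genes was 10.3 ± 1.18% in cross A and 8.30 ± 1.06% in cross B (n = 8, exact permutation p = 0.00482). The number of genes at 1 FPKM also differed, with 10240 ± 107 in A and 10390 ± 142 in B (n = 8, exact permutation p = 0.0331). Neither measure differed detectably between a knockdown group and the control (exact permutation p from 0.143 to 0.8).

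**Figure D2:**
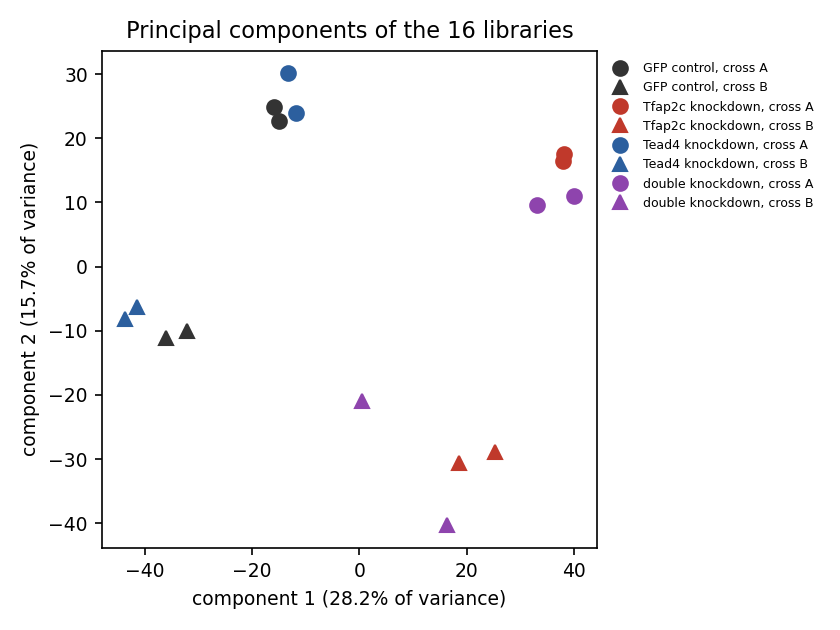
Scores of the 16 libraries on the first principal component (28.2% of variance, x axis) and the second (15.7%, y axis) of log2(FPKM + 1), with color for group and marker shape for cross. Libraries with Tfap2c dsRNA lie to the right of those without it, and cross A lies above cross B.

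The Tfap2c knockdown asks which transcripts of the 8-cell embryo depend on Tfap2c, in a study on when the first cell lineages are set apart. Embryos lost most of Smpdl3a, a sphingomyelinase-like phosphodiesterase gene, of the surface antigen gene Ly6a, and of Dap, BC048679 and the LIM-domain gene Crip1. Receptor and epithelial genes typical of the later trophectoderm, Fgfr2, Cldn4 and Esrrb, fell, and so did the pluripotency genes Tdgf1, Tfcp2l1, Nanog and Pou5f1. The cell-cycle inhibitor gene Cdkn1a rose, and with it other genes of the p53 response. Of 19 polarity genes 5 rose and 3, namely Prkcz, Crb3 and Pard6b, fell, and Ezr, which encodes the cortical linker ezrin, rose.

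Smpdl3a (chromosome 10, 57794544 to 57811830, ENSMUSG00000019872) had the steepest fall, from 128 ± 29.3 to 4.17 ± 5.72 FPKM (log2 change -5.14, adjusted p = 4.15e-06). Ly6a went from 231.5 ± 87.3 to 12.4 ± 12.6 FPKM (log2 change -4.69), Dap from 45.7 ± 11.9 to 1.31 ± 1.7 FPKM (-4.55), BC048679 from 43.4 ± 21.1 to 1.02 ± 1.16 FPKM (-4.48) and Crip1 from 48.5 ± 28.5 to 2.36 ± 2.54 FPKM (-4.08). Among the 5 steepest rises, the cilium gene Tekt2 went from 6.68 ± 2.86 to 44.1 ± 6.39 FPKM (log2 change 2.62, adjusted p = 4.51e-06) and the immediate early gene Ier3 from 0.218 ± 0.13 to 6.28 ± 2.62 FPKM (2.5, adjusted p = 9.17e-06). The transcripts Gm24336 and Gm24044 also passed and are listed at 0 in every control library. These are uncertain, since both are listed at 0 in some libraries and above 40 FPKM in others within each of the other knockdown groups, and Gm24044 is listed at 0 in Tfap2c knockdown B2. Each of these falls and the rises of Tekt2 and Ier3 held in each library of the group against every control library.

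In total 3377 genes changed, 1866 higher and 1511 lower, but which direction was more frequent depended on scaling. After median-ratio rescaling 1537 were higher and 1807 lower, and after quantile normalization 1721 and 1588. Of the 771 that changed by more than 2-fold, 310 were higher and 461 lower. Among the called genes, 3376 moved in the same direction in cross A and in cross B. Genes were called on both crosses together, which favors such agreement, so these counts are no separate support here or below. The Tfap2c depletion itself was partial, and the recovery of simulated changes in this comparison was 29.9% at a log2 change of 0.5 and 94% at 1.

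Some trophectoderm genes moved down, though the list as a whole did not pass with an estimated correlation. Of 24 measured, 9 fell, 0 rose and 15 did not pass, and adjusted over the list alone 9 fell. Fgfr2 (chromosome 7, 130162451 to 130266808, ENSMUSG00000030849), the FGF receptor gene, fell from 28.95 ± 4.94 to 4.69 ± 2.61 FPKM (log2 change -2.49, adjusted p = 6.19e-06). The claudin gene Cldn4 fell from 7.12 ± 0.775 to 0.9865 ± 0.364 FPKM and Esrrb from 8.13 ± 0.727 to 1.95 ± 0.454 FPKM. The camera adjusted p of the list was 0.000986, and 0.247 with an estimated correlation. Gata3, at 2.60 ± 1.24 against 4.90 ± 2.56 FPKM, did not pass (log2 change -0.66, adjusted p = 0.115), but did without Tfap2c knockdown A1 (adjusted p = 0.00863). Cdx2, Sox2 and Tfap2a lay below the expression filter, at no more than 0.341, 0.388 and 0.0276 FPKM in any library.

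Pluripotency genes also moved down, with 12 of 28 lower, 3 higher and 13 not passing. Adjusted over the list alone, 12 were lower and 3 higher. Tdgf1, which encodes the Nodal co-receptor Cripto, fell from 81.5 ± 20.9 to 10.5 ± 3.38 FPKM (log2 change -2.86, adjusted p = 1.84e-06). Tfcp2l1 fell by 2.11 and Sox15 by 0.81 on the log2 scale. Nanog fell from 26.9 ± 1.21 to 8.61 ± 3.22 FPKM (adjusted p = 0.00276) and Pou5f1 from 37.2 ± 4.8 to 17.4 ± 4.39 FPKM (adjusted p = 0.00622). Klf17 was among the 3 that rose, by 1.26. The list's camera adjusted p was 0.00102, and 0.0285 with an estimated correlation.

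Of 22 p53 and stress genes 12 were higher, 0 lower and 10 did not pass. The list did not pass with an estimated correlation. Adjusted over the list alone, 15 were higher and 1 lower. Cdkn1a (chromosome 17, 29090979 to 29100722, ENSMUSG00000023067) rose from 122 ± 62.5 to 376 ± 168 FPKM (log2 change 1.66, adjusted p = 1.98e-06). The SD of both groups spans 2 crosses, in which the control stood at 56.2 and 87.8 FPKM in A and at 197 and 147 FPKM in B. Sesn1 rose from 6.31 ± 0.987 to 12.5 ± 1.06 FPKM and Trp53inp1 from 10.8 ± 4.44 to 21.9 ± 5.46 FPKM. The camera adjusted p was 0.000986, and 0.291 with an estimated correlation.

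Of 28 endocytosis and lysosome genes 14 were lower, 4 higher and 10 did not pass. Adjusted over the list alone, 17 were lower and 4 higher. Psap, which encodes prosaposin, fell from 43.0 ± 5.27 to 16.4 ± 1.68 FPKM and Hexa, a hexosaminidase gene, from 27.2 ± 13 to 7.43 ± 2.78 FPKM, while Lamp2 rose from 258 ± 29.1 to 470 ± 99.2 FPKM. The camera adjusted p was 0.00916, and 0.269 with an estimated correlation.

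Genes of cell shape went in both directions, and none of these lists passed as a whole. The polarity list did not pass (camera adjusted p = 0.556, adjusted over the list alone 6 and 3). The 3 that fell were the atypical protein kinase C gene Prkcz, from 15.95 ± 1.92 to 8.07 ± 1.55 FPKM (adjusted p = 0.000645), Crb3, from 168 ± 16.9 to 106 ± 11.7 FPKM, and Pard6b, from 4.30 ± 1.09 to 2.19 ± 0.541 FPKM (adjusted p = 0.0121, and 0.0768 without the cross covariate). Of 52 actin regulators 7 rose and 14 fell (camera adjusted p = 0.095, adjusted over the list alone 7 and 15). The Arp2/3 subunit gene Arpc1b fell by 2.55 and the tropomyosin gene Tpm4 by 1.25 on the log2 scale, whereas the calponin gene Cnn3 rose by 0.88. The citron kinase gene Cit fell by 1.31 on the log2 scale. Rhoa, at 175 ± 3.92 against 167 ± 18.6 FPKM, did not pass (adjusted p = 0.533). Ezr rose from 2.86 ± 0.848 to 7.90 ± 0.61 FPKM (log2 change 1.23, adjusted p = 0.00288), 1 of the 12 apical cortex genes to rise, and 1 fell (camera adjusted p = 0.715, adjusted over the list alone 1 and 1). Of 18 junction genes 2 rose and 5 fell (camera adjusted p = 0.25, adjusted over the list alone 3 and 5), and of 7 keratin and desmosome genes 1 rose and 1 fell (0.825, adjusted over the list alone 1 and 1).

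Of the 10 YAP-TEAD target genes, 5 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.157, and 0.291 with an estimated correlation). Ajuba rose from 3.00 ± 0.264 to 9.57 ± 1.03 FPKM (log2 change 1.40, adjusted p = 2.35e-06), Ctgf from 3.71 ± 1.7 to 10.8 ± 1.26 FPKM (adjusted p = 0.0012) and Amotl2 from 8.27 ± 2.09 to 14.5 ± 5.58 FPKM (adjusted p = 0.00236, and 0.0681 without the cross covariate). Of 23 Hippo pathway genes 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.84), and the TEAD cofactor gene Vgll4 fell by 1.34 (adjusted p = 0.000103, and 0.0656 without the cross covariate). Yap1 did not pass, at 4.62 ± 1.44 against 4.59 ± 0.444 FPKM (adjusted p = 0.934). Of the 2 measured AP-2 and TEAD family genes Tead1 rose by 0.71, and a list of this size was not tested as a whole.

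Of 19 sterol synthesis genes 7 were higher, 1 lower and 11 did not pass. Adjusted over the list alone, 9 were higher and 2 lower. Sqle, which encodes squalene epoxidase, rose from 23.9 ± 5.49 to 49.3 ± 3.48 FPKM. The list's camera adjusted p was 0.095, 0.509 with an estimated correlation, and 0.0457 without Tfap2c knockdown B2. Of 30 G2/M genes 2 rose and 8 fell (camera adjusted p = 0.469), and the falls included Fbxo5, an inhibitor of the anaphase-promoting complex, by 1.27 and the kinetochore motor gene Cenpe by 0.59. Of 12 interferon and dsRNA response genes 3 rose and 3 fell (camera adjusted p = 0.578, adjusted over the list alone 3 and 4). Irf9 fell from 7.19 ± 1.4 to 1.40 ± 0.557 FPKM and Oasl2 from 12 ± 4.17 to 3.44 ± 1.2 FPKM.

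The remaining lists held few calls. Counts of genes higher and lower were 2 and 1 of 8 for primitive endoderm (camera adjusted p = 0.825), 3 and 1 of 30 for oocyte transcripts (0.552), and 5 and 1 of 31 for 2-cell transcripts (0.715). They were 0 and 1 of 15 for mitochondrially encoded transcripts (0.469), 4 and 4 of 86 for ribosomal proteins (0.8), and 12 and 5 of 82 for oxidative phosphorylation (0.987). They were 0 and 1 of 36 for the proteasome (0.476) and 2 and 3 of 17 for glycolysis (0.925). Adjusted over the list alone, ribosomal proteins gave 0 and 0, mitochondrial transcripts 0 and 0, and oxidative phosphorylation 11 and 5, with the other counts as given. Too small for a test as a whole, cumulus markers gave 2 higher of 4 (and 1 lower adjusted over the list alone), sperm markers 0 of 2 and blood markers 2 of 4. The 2 blood markers were the alpha-globin genes Hba-a1, from 12.4 ± 4.42 to 32.9 ± 10.9 FPKM (adjusted p = 0.00155), and Hba-a2, from 7.71 ± 3.01 to 18.15 ± 4.26 FPKM (adjusted p = 0.00136). Their near-identical sequences leave the division of reads between them uncertain. Median and mean differed in sign for the apical cortex, keratin, Hippo, 2-cell and G2/M lists. For oxidative phosphorylation and glycolysis both were above 0 while the test pointed down.

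The Tead4 knockdown asks which transcripts depend on Tead4 at this stage. Depleted embryos lost Dab2, an endocytic adaptor gene, S100a11, which encodes a calcium-binding protein, and the efflux transporter gene Abcb1a. Known targets and regulators of YAP and TEAD fell too, among them Amotl2, Ctgf, Cyr61 and Lats2. The keratin gene Krt18, the myosin gene Myo1c and the annexin gene Anxa2 fell, and Ezr rose as it did in the Tfap2c knockdown.

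Among the 5 steepest falls, S100a11 went from 143.7 ± 90.6 to 10.35 ± 10.4 FPKM (log2 change -4.04, adjusted p = 2.84e-05). Dab2 (chromosome 15, 6299788 to 6440715, ENSMUSG00000022150) went from 72.9 ± 13.9 to 4.70 ± 3.7 FPKM (-3.86, adjusted p = 4.36e-06) and Abcb1a from 19.25 ± 4.04 to 1.01 ± 0.466 FPKM (-3.34, adjusted p = 8.68e-08). Amotl2 (chromosome 9, 102717091 to 102733418, ENSMUSG00000032531), whose product binds YAP, went from 8.27 ± 2.09 to 0.2545 ± 0.237 FPKM (-2.88, adjusted p = 5.48e-08). Each of these falls held in each library against every control library. Among the 5 steepest rises were the defensin gene Defb19, from 0.5145 ± 0.403 to 5.54 ± 1.9 FPKM (log2 change 2.11), and the stress-response gene Nupr1, from 40.8 ± 3.58 to 128 ± 58.8 FPKM (1.51, adjusted p = 0.00139).

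In total 700 genes changed, 383 higher and 317 lower. The split depended on scaling, with 262 higher and 414 lower after median-ratio rescaling and 288 and 396 after quantile normalization. Of the 172 that changed by more than 2-fold, 58 were higher and 114 lower. All 700 moved in the same direction in both crosses, on which they were called together. Without GFP B2 the count was 407 and without Tead4 knockdown B1 it was 446. The recovery of simulated changes was 43.3% at a log2 change of 0.5 and 86.6% at 1.

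YAP-TEAD target genes moved down, with 4 of 10 lower, 0 higher and 6 not passing, and with the same counts adjusted over the list alone. Ctgf (chromosome 10, 24595442 to 24598683, ENSMUSG00000019997) fell from 3.71 ± 1.7 to 0.149 ± 0.211 FPKM (log2 change -1.96, adjusted p = 0.000523), Cyr61 fell by 1.91 and the kinase gene Lats2 by 1.65. For the list as a whole the camera adjusted p was 5.47e-05, and 0.0104 with an estimated correlation. Of 23 Hippo pathway genes 5 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00436, and 0.0334 with an estimated correlation). This list shares members with the YAP-TEAD targets, Amotl2 and Lats2 among them, so the 2 results are not separate. Vgll4 fell by 1.64 (adjusted p = 0.000111, and 0.1 without the cross covariate), whereas Wwtr1, which encodes the YAP relative TAZ, rose from 14.95 ± 2.76 to 26.3 ± 4.81 FPKM. Yap1 did not pass, at 4.95 ± 0.973 FPKM (adjusted p = 0.867).

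Of 18 junction genes 2 fell and 0 rose, and adjusted over the list alone 5 fell (camera adjusted p = 0.00822, and 0.0765 with an estimated correlation). They were Marveld2, which encodes tricellulin, by 1.33, and the catenin gene Ctnna1 by 0.52 (adjusted p = 0.00992, and 0.0596 without the cross covariate). Of 52 actin regulators 6 fell and 0 rose. Adjusted over the list alone, 10 fell and 3 rose. Cnn3 fell from 149 ± 18.8 to 51.9 ± 0.958 FPKM (adjusted p = 4.35e-07) and the alpha-actinin gene Actn4 from 35.1 ± 3.52 to 15.2 ± 2.74 FPKM. The camera adjusted p was 0.0153, 0.643 with an estimated correlation, and 0.072 without Tead4 knockdown A2. Of 12 apical cortex genes 1 rose and 2 fell, and adjusted over the list alone 4 fell and 1 rose. Its camera adjusted p of 0.0712 came to 0.0495 without GFP A1 and 0.0462 without Tead4 knockdown B2. Anxa2 fell by 1.49 and the myosin gene Myo1c by 1.21, and Ezr rose from 2.86 ± 0.848 to 9.80 ± 3.89 FPKM (log2 change 1.44, adjusted p = 0.00447). Rhoa rose from 167 ± 18.6 to 205 ± 24.6 FPKM (log2 change 0.29, adjusted p = 0.0369, and 0.0839 after median-ratio rescaling). That call was lost, at adjusted p from 0.0683 to 0.113, without GFP A1, A2 or B2 or Tead4 knockdown A1, B1 or B2. None of the 19 polarity genes passed by limma, also adjusted over the list alone (camera adjusted p = 0.455). Pard6b stood at 4.05 ± 2.26 FPKM (adjusted p = 0.707).

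Trophectoderm genes split, with 6 of 24 lower and 5 higher, and adjusted over the list alone 8 lower and 5 higher. The camera adjusted p of 0.0412 pointed down. It was 0.361 with an estimated correlation, 0.0707 without GFP B1, 0.072 without Tead4 knockdown A2 and 0.0627 after median-ratio rescaling. Gata3 fell from 4.90 ± 2.56 to 1.70 ± 1.03 FPKM (log2 change -1.08, adjusted p = 0.0463). That call was lost, at adjusted p from 0.0811 to 0.131, without GFP A1, B1 or B2 or Tead4 knockdown A1, A2 or B1. The keratin gene Krt18 fell from 19 ± 8.58 to 4.94 ± 3.26 FPKM. Of 28 pluripotency genes 1 rose and 2 fell, and adjusted over the list alone 3 and 2 (camera adjusted p = 0.57). Neither Nanog (35.4 ± 12.8 FPKM, adjusted p = 0.684) nor Pou5f1 (38.2 ± 7.81 FPKM, adjusted p = 0.975) passed.

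Of 22 p53 and stress genes 4 were higher and 0 lower, and adjusted over the list alone 7 were higher. The list did not pass with an estimated correlation. Cdkn1a rose to 287 ± 145 FPKM (log2 change 1.23, adjusted p = 0.000145, and 0.229 without the cross covariate) and Ddit3 from 5.67 ± 2.65 to 10.0 ± 2.34 FPKM (adjusted p = 0.00808, and 0.144 without it). Sesn1 rose by 0.47 (adjusted p = 0.0168), a call lost without GFP A1 (0.059) or GFP B2 (0.0503). The list's camera adjusted p was 0.00131, and 0.307 with an estimated correlation. The interferon gene Irf9 rose from 7.19 ± 1.4 to 14.4 ± 3 FPKM and the cathepsin gene Ctsb from 90.0 ± 4.13 to 169 ± 12.6 FPKM. Of the 30 G2/M genes 2 rose and 3 fell (camera adjusted p = 0.128, and 0.046 without GFP B1), with Cenpe lower by 0.79. Of the 31 2-cell transcripts 0 rose and 1 fell (camera adjusted p = 0.0537). That list passed without GFP B1 (0.00956), GFP B2 (0.0373), Tead4 knockdown A1 (0.00574) or Tead4 knockdown A2 (0.0285). Mitochondrial transcripts (0.0798) passed without GFP A1 (0.0307) or Tead4 knockdown A1 (0.0124), and ribosomal proteins (0.57) without GFP A2 (0.0108). Hba-a2 rose by 0.82 (adjusted p = 0.0475, and 0.0717 after median-ratio rescaling), a call lost at adjusted p from 0.0686 to 0.144 without GFP A1, A2 or B2 or Tead4 knockdown A1, A2 or B1. Median and mean differed in sign for the polarity, keratin, sterol and endocytosis lists. For the pluripotency, primitive endoderm and ribosomal lists both were above 0 while the test pointed down.

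The double knockdown asks what the loss of both factors does. Ly6a, Smpdl3a and Dap, which fell in the Tfap2c knockdown, lay far below the control here too, and so did Gsto1, a glutathione transferase gene. Trophectoderm genes including Aqp3, Fgfr2 and Gata3 fell, and so did Amotl2. Of 31 transcripts typical of the 2-cell stage 10 rose, among them B020004J07Rik, though the list did not pass with an estimated correlation.

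Ly6a fell to 13.6 ± 15.1 FPKM (log2 change -4.61, adjusted p = 5.4e-06), Smpdl3a to 10.6 ± 9.78 FPKM (-3.90) and Dap to 3.41 ± 3.01 FPKM (-3.62). Gsto1 fell from 364 ± 198 to 33.7 ± 35.9 FPKM (-3.85). Among the 5 steepest rises was the ubiquitin hydrolase gene Uchl1, from 7.12 ± 2.78 to 41.1 ± 22.7 FPKM (log2 change 2.29, adjusted p = 0.00233, and 0.0811 without the cross covariate). In total 2872 genes changed, 1583 higher and 1289 lower, or 1371 and 1493 after median-ratio rescaling and 1475 and 1362 after quantile normalization. Of the 673 that changed by more than 2-fold 260 were higher and 413 lower. Among the called genes, 2871 moved in the same direction in both crosses, on which they were called together. The recovery of simulated changes was 34.3% at a log2 change of 0.5 and 80.6% at 1.

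**Figure D3:**
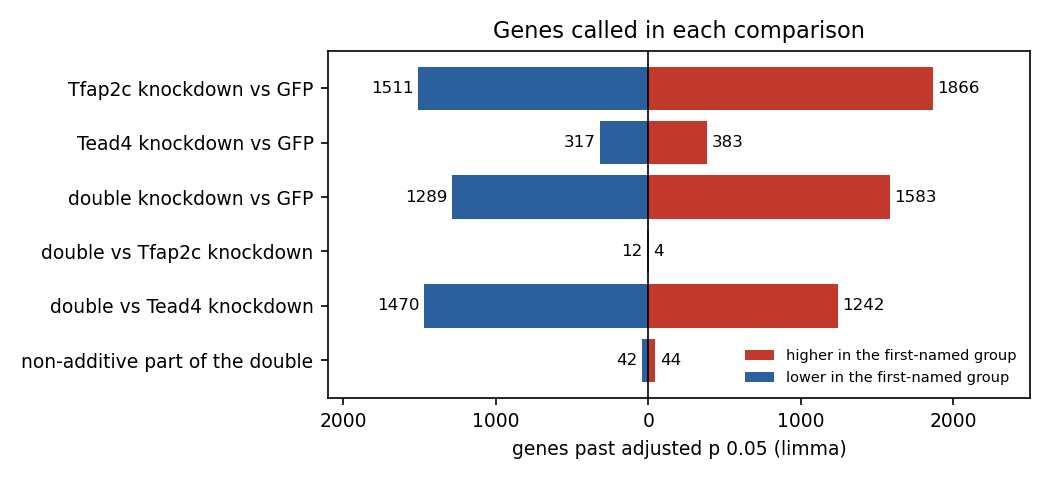
Number of genes higher (above 0) and lower (below 0) at adjusted p under 0.05 in limma, out of 11422 tested, for each of the 6 comparisons. The comparisons that add Tfap2c dsRNA give 3377, 2872 and 2712 genes, Tead4 dsRNA alone 700, and Tead4 dsRNA added to Tfap2c dsRNA 16.

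Of 24 trophectoderm genes 11 were lower and 1 higher, and adjusted over the list alone 13 lower and 1 higher. The list did not pass with an estimated correlation. The water channel gene Aqp3 fell from 18.1 ± 4.09 to 1.99 ± 1.15 FPKM (log2 change -2.73, adjusted p = 1.38e-05), Fgfr2 by 2.63 and Cldn4 by 2.30. Gata3 fell to 1.67 ± 1.08 FPKM (log2 change -1.12, adjusted p = 0.0133). The list's camera adjusted p was 1.57e-05, and 0.0698 with an estimated correlation. Of 28 pluripotency genes 10 fell and 3 rose, and adjusted over the list alone 12 fell and 5 rose (camera adjusted p = 0.0117, and 0.0698 with an estimated correlation). Tdgf1 fell by 2.30, Sox15 by 0.67 and Pou5f1 by 1.23 (16.6 ± 9.35 FPKM, adjusted p = 0.00296), and Klf17 rose from 54.55 ± 19.4 to 133.5 ± 50.5 FPKM. Nanog did not pass, at 19.4 ± 11.2 FPKM (adjusted p = 0.194).

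Of 31 2-cell transcripts 10 rose and 0 fell, and adjusted over the list alone 15 rose. B020004J07Rik rose from 2.78 ± 0.272 to 14.4 ± 7.75 FPKM (log2 change 1.87, adjusted p = 0.00042). Zfp352 rose from 4.41 ± 4.24 to 13.8 ± 15.4 FPKM (1.31, adjusted p = 0.0034, and 0.39 without the cross covariate), with 36.0 and 12.3 FPKM in B1 and B2 and 4.29 and 2.44 FPKM in A1 and A2. The list's camera adjusted p was 0.000673, and 0.499 with an estimated correlation. Several of its members are copies in gene clusters, whose reads cannot be placed with certainty.

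The p53 and stress genes were higher for 11 of 22 and lower for 0, and adjusted over the list alone 13 were higher. Cdkn1a rose to 367 ± 182 FPKM (log2 change 1.59, adjusted p = 4.92e-06), Sesn1 by 0.98, Trp53inp1 by 1.17 and Ddit3 by 1.01. As a list their camera adjusted p was 0.000387, and 0.217 with an estimated correlation. Of 28 endocytosis and lysosome genes 12 fell and 3 rose, and adjusted over the list alone 12 fell and 6 rose (camera adjusted p = 0.0236, and 0.217 with an estimated correlation). Psap fell by 1.27 and Lamp2 rose by 0.91. Of 52 actin regulators 13 fell and 5 rose, and adjusted over the list alone 13 fell and 6 rose. Their camera adjusted p of 0.049 came to 0.61 with an estimated correlation, 0.0947 without GFP B2, 0.0502 without double knockdown A1 and 0.104 without double knockdown B1. Tpm4 fell by 1.53 on the log2 scale.

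Among genes of cell shape, Prkcz fell by 0.87 (adjusted p = 0.00107), Myo1c by 0.79, Cit by 1.07 and Marveld2 by 0.96. Pard6b fell to 2.40 ± 0.546 FPKM (log2 change -0.63, adjusted p = 0.0281), a call lost at adjusted p from 0.0537 to 0.0948 without GFP A1, A2 or B2 or double knockdown B1. Crb3 fell to 125 ± 24.1 FPKM (-0.44, adjusted p = 0.0235), lost at adjusted p from 0.0622 to 0.0749 without GFP A1 or B2 or double knockdown A1, A2 or B2. Ezr, at 5.41 ± 3.32 FPKM, did not pass (adjusted p = 0.0948, and 0.0475 without GFP A2). Neither Rhoa (176 ± 9.25 FPKM, adjusted p = 0.506) nor Yap1 (adjusted p = 0.675) passed. Of the 10 YAP-TEAD targets 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.517). Ajuba rose by 1.05, Amotl2 fell to 2.47 ± 0.887 FPKM (log2 change -1.42) and Cyr61 fell by 1.30. The sterol gene Sqle rose by 1.11, Fbxo5 fell by 1.05 and Irf9 by 1.53. The globin genes Hba-a1 and Hba-a2 rose by 1.39 and 1.16. The G2/M list (0.112) passed without GFP B1 (0.0482) and the ribosomal list (0.312) without GFP A2 (0.0172). Median and mean differed in sign for the interferon and glycolysis lists, and for oxidative phosphorylation both were above 0 while the test pointed down.

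**Figure D4:**
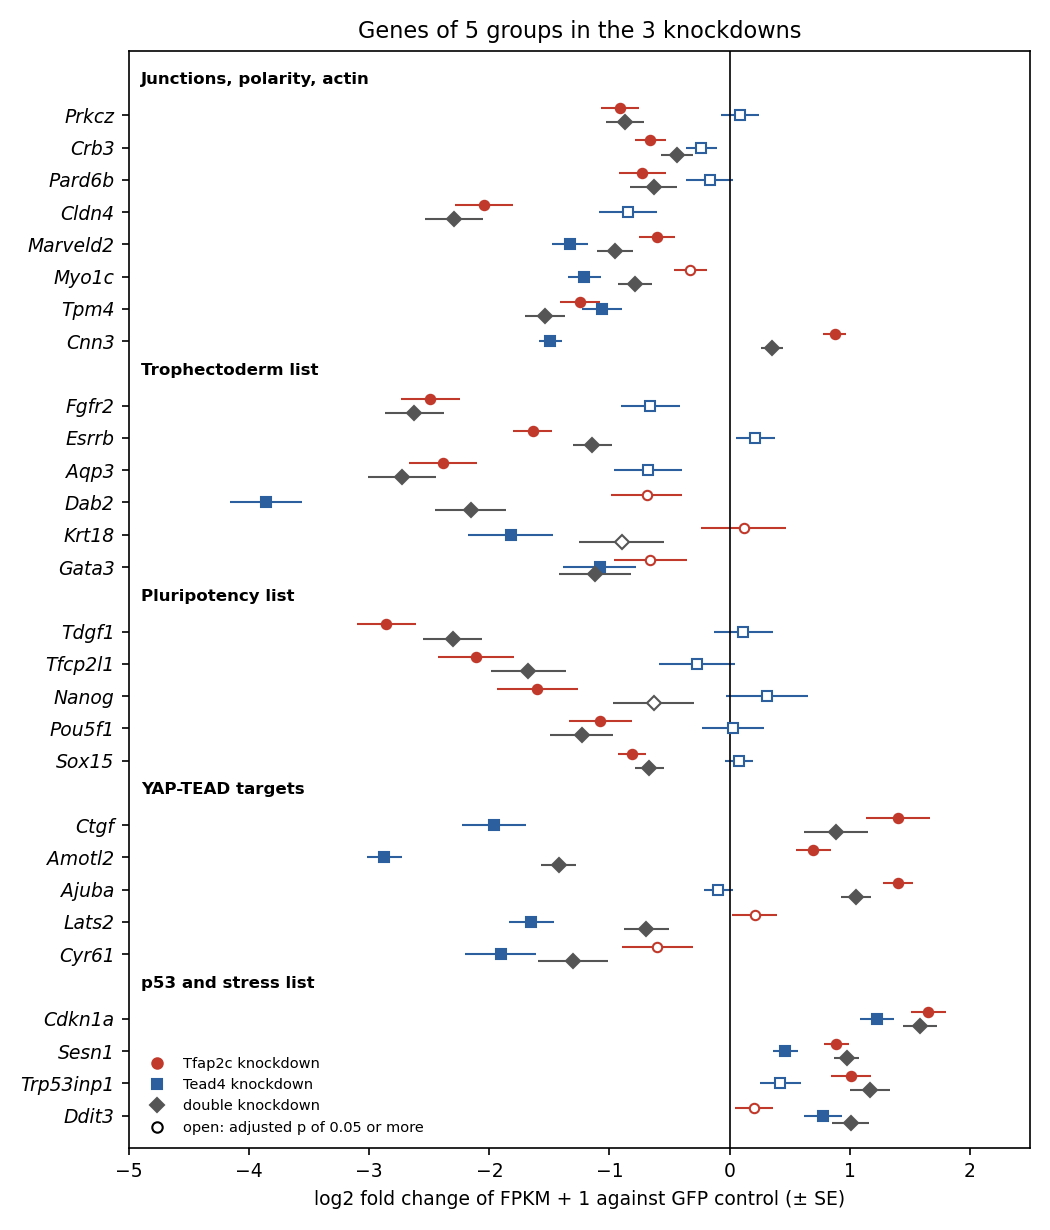
Log2 change against the GFP control (x axis, bars for standard error) of 28 named genes in 5 groups for the 3 knockdowns, with filled points at adjusted p under 0.05 and open points above it. Amotl2 and Cnn3 lie on opposite sides of 0 in the Tfap2c and the Tead4 knockdown.

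The double knockdown was set against the Tfap2c knockdown to see what Tead4 dsRNA adds where Tfap2c is already depleted. Amotl2 fell from 14.5 ± 5.58 to 2.47 ± 0.887 FPKM (log2 change -2.12, adjusted p = 4e-06). Tead4 itself fell by 1.52 (adjusted p = 0.0257) and Ier3 by 1.65 (adjusted p = 0.0257). The Tead4 call was lost, at adjusted p from 0.0508 to 0.0796, without Tfap2c knockdown A2, B1 or B2 or double knockdown A1, A2 or B1. The Ier3 call was lost, at adjusted p from 0.0508 to 0.0796, without Tfap2c knockdown A1, A2 or B1 or double knockdown A1, A2 or B2. Tfap2c mRNA did not differ detectably (adjusted p = 0.954). In total 16 genes changed, 4 higher and 12 lower, or 5 and 9 after median-ratio rescaling, and 1087 had an unadjusted p under 0.05. The count lay between 1 and 10 when any library of the 2 groups was left out. All 16 had the same direction in both crosses, on which they were called together. Over all tested genes the changes in cross A and in cross B correlated at r = 0.101. In simulated data this comparison recovered 34.3% of changes of 0.5 and 79.1% of changes of 1 on the log2 scale.

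In this comparison the YAP-TEAD targets were lower as a list, with 1 of 10 lower and 0 higher (camera adjusted p = 6.05e-07, and 0.00325 with an estimated correlation), and adjusted over the list alone 3 were lower. The 2-cell list pointed up and passed only at the preset correlation, with 1 of 31 higher (camera adjusted p = 3.22e-07, and 0.328 with an estimated correlation). Adjusted over the list alone, 5 were higher. The Hippo list, with 1 of 23 lower, passed at 0.0164 (0.082 with an estimated correlation, 0.0531 without Tfap2c knockdown B1 and 0.0905 without double knockdown A2). Its lower member, Amotl2, is also that of the YAP-TEAD list, so these are not separate results. The apical cortex list, with 1 of 12 lower, passed at 0.0258. It did not with an estimated correlation (0.107) or without Tfap2c knockdown A1 (0.0763), A2 (0.0658) or B1 (0.125) or double knockdown A2 (0.0905). The ribosomal list, with none of its members passing, passed at 0.00378. It did not with an estimated correlation (0.713) or without Tfap2c knockdown A1 (0.19) or A2 (0.112) or double knockdown A1 (0.086). Trophectoderm genes (0.269) passed without Tfap2c knockdown B2 (0.0211) or double knockdown B2 (0.0372), pluripotency genes (0.0903) without double knockdown A1 (0.039), and oxidative phosphorylation (0.511) without Tfap2c knockdown B1 (0.000314). Median and mean differed in sign for the actin and endocytosis lists.

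The double knockdown was set against the Tead4 knockdown to see what Tfap2c dsRNA adds where Tead4 is already depleted. Transcripts lost in the Tead4 knockdown were higher with both, namely the aldo-keto reductase gene Akr1b8, from 2.33 ± 1.39 to 32.3 ± 2.73 FPKM (log2 change 3.41, adjusted p = 9.18e-07), Abcb1a, from 1.01 ± 0.466 to 14.8 ± 3.87 FPKM (2.97), and Ctgf, from 0.149 ± 0.211 to 7.41 ± 2.14 FPKM (2.85). The steepest falls were those of the calmodulin-like gene Calm5, from 47.6 ± 8.83 to 2.42 ± 3.36 FPKM (-4.27), BC048679 (-4.06) and Smpdl3a (-4.03). Tfap2c mRNA fell by 1.06 and Tead4 mRNA did not differ detectably (adjusted p = 0.498). In total 2712 genes changed, 1242 higher and 1470 lower, or 1309 and 1418 after median-ratio rescaling and 1393 and 1358 after quantile normalization. Of the 2712, 2710 had the same direction in both crosses, on which they were called together. Of 31 2-cell transcripts 17 were higher and 1 lower (camera adjusted p = 3.75e-06, and 0.532 with an estimated correlation), and adjusted over the list alone 19 and 1. Of 24 trophectoderm genes 1 was higher and 9 lower (0.0125, and 0.366 with an estimated correlation), and adjusted over the list alone 2 and 11. Of 10 YAP-TEAD targets 5 were higher and 1 lower, also adjusted over the list alone (0.013, and 0.169 with an estimated correlation). Pluripotency genes (0.0721) passed without Tead4 knockdown A2 (0.0476) or double knockdown B1 (0.0471) or B2 (0.0249). For the keratin list median and mean differed in sign.

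The double knockdown departed from the sum of the single knockdowns for a small set of genes. S100a11 fell in each single knockdown, by 2.62 and 4.04, but by 2.73 in the double, which left it 3.93 above the sum on the log2 scale (adjusted p = 0.00851, and 0.229 without the cross covariate). As log2(FPKM + 1) cannot go below 0, S100a11 could reach that sum only near 0 FPKM. Its place above the sum may thus come partly from this floor. How many of the genes above the sum this touches was not tested. Dab2 lay 2.40 above the sum (adjusted p = 0.0262). Zfp771, a zinc finger gene, rose in each single knockdown and not in the double, 2.71 below the sum (non-additive log2 change -2.71, adjusted p = 0.00851), and Ezr lay likewise below it (-2.04, adjusted p = 0.0279). The Dab2 call was lost, at adjusted p from 0.0514 to 0.0626, without GFP A2 or B2, Tead4 knockdown A1 or A2, Tfap2c knockdown A2, B1 or B2, or double knockdown A1. The Ezr call was lost, at adjusted p from 0.0502 to 0.0708, without GFP B2, Tead4 knockdown A1, B1 or B2, any Tfap2c knockdown library, or double knockdown A1. The non-additive part of Tead4 mRNA was 1.04 (adjusted p = 0.184). In total 86 genes departed, 44 above and 42 below the sum, or 52 and 23 after median-ratio rescaling and 47 and 20 after quantile normalization. The count lay between 12 and 55 without any library except GFP B1, double knockdown A2 or double knockdown B2, and reached 113 without double knockdown A2. In simulated data this contrast recovered 62.7% of changes of 1 on the log2 scale.

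The single knockdowns share their control libraries, so their changes were compared beside simulated unchanged groups. Across genes, which are not independent replicates, the changes in the Tfap2c and Tead4 knockdowns had a Pearson r of 0.247, against 0.51 ± 0.142 in simulations with no effect. Their covariance was 0.0566 against a simulated 0.0427, a difference of 0.014. Real effects add variance that the simulations lack, which can lower r, so the values of r are not directly comparable. No spread of the simulated covariance is given, so that difference cannot be judged. With the controls split so that the comparisons shared none, r was 0.0916 and 0.0353. Of the 375 genes called in both, 135 were higher in both, 122 lower in both and 118 opposite. Independent lists of these sizes would share 62.6 and 41.9, figures that leave out the shared controls, and none was computed for the opposite genes. Simulated unchanged groups shared 0, but with no effect few genes can be called in them. That value therefore does not tell how much of the overlap comes from the shared controls. The 257 genes with the same direction became 170 without GFP A1, 138 without GFP B2 and 170 without Tead4 knockdown B1. Genes with opposite changes, chosen after their values were seen, include Irf9, lower by 1.79 in the Tfap2c and higher by 0.91 in the Tead4 knockdown, and Cnn3, higher by 0.88 and lower by 1.49. The double knockdown shared 1206 higher and 1061 lower genes with the Tfap2c knockdown (r = 0.828, covariance 0.267 against a simulated 0.0419), with 1 opposite. It shared 157 higher and 170 lower with the Tead4 knockdown (r = 0.346, covariance 0.0756 against 0.0429), with 65 opposite. Of the 700 genes called in the Tead4 knockdown, 517 had the same direction from the Tfap2c to the double knockdown.

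The crosses differed in many transcripts at once. In the same fit 3823 genes differed between crosses, 1965 higher in B and 1858 lower. Whether the cross or a batch of embryos or libraries lies behind them cannot be told from the labels. A response that differs between crosses was tested by the interaction of injection and cross. By limma 0 genes passed for the Tfap2c, the Tead4 and the double knockdown, with 1888, 797 and 1284 genes at an unadjusted p under 0.05. These counts depended on settings, with up to 55, 32 and 26 genes when no expression filter was applied, and 11, 0 and 7 after median-ratio rescaling. A split by cross of the Tfap2c and double knockdown libraries, added later, gave 170 genes, and that of the control and Tead4 libraries gave 52. Both set the cross difference with Tfap2c dsRNA against that without it, so a response that differs between crosses is not excluded. In simulated data 84% of interactions of 2 on the log2 scale were recovered for the Tfap2c knockdown, so smaller differences between crosses may have gone undetected. Across genes, changes measured in cross A and in cross B correlated at r = 0.489 for the Tfap2c, 0.229 for the Tead4 and 0.439 for the double knockdown.

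The 23 lists tested gave 4, 6 and 6 passing lists in the Tfap2c, Tead4 and double knockdown with the preset correlation, and 1, 2 and 0 with an estimated correlation. Other divisions of the same 8 libraries gave up to 8, 9 and 8 passing lists.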

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

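The splits of libraries, and the tests of weaker Tead4 depletion, a shared direction with the Tfap2c knockdown, low control libraries, scaling, slower development and a need for Tead4, were chosen only after the results were seen.

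Single libraries stood far from the other 3 of their group, across most of the group's whole range, in 15 of 300 groups looked at, and chance alone gives about 1 in 20. In Tfap2c knockdown B1, Smpdl3a was 12.7 FPKM against 1.08 to 1.6 in the other libraries, Arpc1b 1.69 against 0.162 to 0.257 and Calm5 9.35 against 0 to 0.364. In the other Tfap2c knockdown libraries, Hba-a1 was 16.9 FPKM in B2 against 35.3 to 40.8, and Marveld2 2.13 in A1 against 2.72 to 2.85. In the double knockdown, Pard6b was 3.21 FPKM in B2 against 2.06 to 2.21, Cit 4.59 in A2 against 8.77 to 9.44 and Hba-a2 27.1 in A1 against 14.1 to 15.6. In Tead4 knockdown B2, Ajuba was 2.07 FPKM against 2.92 to 3.08 and Ctgf 0.464 against 0.0292 to 0.0637. In the control, Pou5f1 was 30 FPKM in A2 against 38.9 to 40.5, Sesn1 7.78 in A2 against 5.67 to 5.92 and Uchl1 3 in B2 against 7.95 to 8.92. Library measures that stood apart were the genes at 1 FPKM in GFP B1, 10504 against 10049 to 10079, and the mitochondrial share in GFP A2, 12.1% against 8.95% to 9.43%. The most from 1 library was 3, in Tfap2c knockdown B1 and in GFP A2.

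Over all splits, the real one gave the most genes in 4 of the comparisons. Among 35 splits of the same 8 libraries into groups of 4, 1 gave as many genes, the real one, for the Tfap2c knockdown (3377 genes, highest other split 4), the Tead4 knockdown (700, highest other 52), the double knockdown (2872, highest other 3) and the double against the Tead4 knockdown (2712, highest other 2). For the double against the Tfap2c knockdown 2 of 35 splits gave 16 genes or more, so chance cannot be excluded over all splits. The other was the split by cross, with 170 genes. The fit still took a term for cross from the GFP and Tead4 libraries. The 170 thus measure how the cross difference with Tfap2c dsRNA departs from that without it, and not chance. The 52 of the Tead4 knockdown came from the split by cross too, which sets the same cross differences against each other. Only 18 of the 35 splits keep 2 libraries of each cross in each group, too few for a share under 0.05. As the fit holds a term for cross, only these are like the real split, and their smallest possible share is 0.0556. By splits alone chance is thus not excluded for any comparison. Among the 18 the highest other gave 4 genes for the Tfap2c, 1 for the Tead4 and 3 for the double knockdown. It gave 1 each for the double against the Tfap2c and against the Tead4 knockdown. For the non-additive part 4 of 100 splits gave 86 genes or more, the real one included, and the highest other gave 2408. Such a count points to a structure of the samples, since these splits mix the knockdown effects into the groups, so whether chance can be excluded is left open. For the number of passing lists chance cannot be excluded. As many lists passed in 20 of 35 splits for the Tfap2c knockdown (4 lists, highest other 8), 7 of 35 for the Tead4 knockdown (6, highest other 9) and 8 of 35 for the double knockdown (6, highest other 8).

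Tead4 dsRNA changed 700 genes against the control but 16 on the Tfap2c-depleted background. For 500 genes picked in libraries A1 and B1, the effect of Tead4 dsRNA was averaged over A2 and B2 in the direction of the pick. It was 0.754 without Tfap2c dsRNA and 0.168 with it, so 22.3% (SE 3.33) was kept, and 10% (SE 4.46) with the library pairs exchanged. These SEs, and that of the share at 10 FPKM below, are over genes. Genes of the same libraries are not replicates, so the SEs understate the error. Weaker Tead4 depletion may add to the small effect kept, but 59.4% (SE 9.13) of the log2 fall of Tead4 was kept. That is more than the share of the gene effect in both picks. How gene effects scale with the fall of Tead4 mRNA is unknown, so whether weaker depletion is the whole cause stays open. Values near the floor of the log2 scale could shrink differences, yet 218 picked genes with a mean of at least 10 FPKM kept 35.4% (SE 4.65), under the 50% predicted for that cause. With an SE over genes only, that cause is not settled. A biological candidate is that Tfap2c depletion already moves these genes the same way, and 26.5% of their size was seen in the Tfap2c knockdown (0.199 of 0.754, and 0.161 of 0.691 with the library pairs exchanged), under the share predicted for that cause but not clearly under the lower limit set against it.

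Of 22 p53 and stress genes 12, 4 and 11 passed as higher in the Tfap2c, Tead4 and double knockdown, and the list mean change lay 0.502, 0.332 and 0.498 (log2) above that of all tested genes, but the list did not pass with an estimated correlation (adjusted p = 0.291, 0.307 and 0.217). Control libraries low by chance could give this, since all comparisons share them, and this stays open, as 2 of 784 choices of 4 libraries lay as far below the other 12 as the GFP group, a share of 0.00255, or 0.0587 after multiplying by the 23 lists tested. Scaling of the deposited FPKM is unlikely to be the cause, since the smallest of the 3 mean changes, not taken relative to other genes, moved from 0.377 to 0.331 (SE 0.0953) with quantile normalization. Slower development of knockdown embryos might raise stress genes, and then maternal and 2-cell transcripts would be higher in each group. Relative to all tested genes, maternal means were 0.167, 0.108 and 0.216 (SE 0.0709) for Tfap2c, Tead4 and double, and 2-cell means 0.102, -0.201 and 0.907 (SE 0.223), of which the Tead4 value is too uncertain to decide.

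Of 10 YAP-TEAD target genes 5 rose in the Tfap2c knockdown and 4 fell in the Tead4 knockdown, although the list itself did not pass in the former (camera adjusted p = 0.157). Scaling could shift such means, but quantile normalization moved them from 0.426 and -0.839 to 0.383 and -0.886 (SE 0.0477), with opposite signs throughout. A single library is unlikely to be the cause, since the difference of 1.28 between the means, here relative to all tested genes, stayed at 1.19 or more whichever library was left out (exact permutation p = 0.0286). A biological candidate is that the rise after Tfap2c depletion needs Tead4. The 5 members that rose gained 1.23 on average from the Tead4 to the double knockdown and 0.982 in the Tfap2c knockdown, with Gadd45b (0.01) as the exception. This goes against a full need for Tead4, though some Tead4 mRNA was left. The largest gains, of Ctgf (2.85) and Amotl2 (1.45), started near 0 FPKM in the Tead4 knockdown, while Ajuba gained 1.15 and Tead1 0.69. From the Tfap2c to the double knockdown the list was lower, and Amotl2 fell below the control. Whether the rise needs Tead4 in part stays open.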

How the results depend on the processing

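Of the results for named genes, those called in the fit as chosen kept direction and call in 3066 cases over all alternatives and lost the call in 219. Those not called stayed so in 1403 cases and gained a call in 42. For lists the numbers were 435 kept and 68 lost among those called, and 1854 kept and 46 gained among the others. Reversals were seen for 2 lists. Oxidative phosphorylation in the Tfap2c knockdown pointed up in cross A alone (nuclear-encoded oxidative phosphorylation, adjusted p = 0.00519), and cytosolic ribosomal proteins in the double against the Tfap2c knockdown pointed up in cross B alone (adjusted p = 0.814). The cause was not tested.

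Without the cross covariate the counts were 2165 genes for the Tfap2c, 279 for the Tead4 and 1786 for the double knockdown, and 3, 1644 and 7 for the double against Tfap2c, the double against Tead4 and the non-additive part. The 3823 genes that differ between crosses then add to the spread within groups. In cross A alone the counts were 1776, 250, 1816, 2, 1404 and 2, and in cross B alone 2218, 81, 1227, 13, 1533 and 3, from 8 of the 16 libraries. The genes called in both single knockdowns with the same direction numbered 90 without the covariate, 97 in cross A and 25 in cross B, and 165 with no filter. In cross A alone 7 lists passed in the Tfap2c knockdown and in cross B alone 8. With an estimated correlation 1, 2 and 0 lists passed in the Tfap2c, Tead4 and double knockdown. Target mRNA kept its direction in each cross, with 2 libraries against 2, for which the smallest exact permutation p is 0.333. In crosses A and B the log2 change of Tfap2c was -1.42 and -0.80 in the Tfap2c knockdown and -1.28 and -0.87 in the double. That of Tead4 was -2.78 and -2.32 in the Tead4 knockdown and -2.79 and -1.82 in the double.

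The 16 genes of the double against the Tfap2c knockdown became 4 with a pseudocount of 0.1, 31 with 5, 4 with no filter, 25 with array weights and 2 with only the groups compared in the fit. The 86 of the non-additive part became 14 with no filter. The cause was not tested. A response that differs between crosses was called for no gene in the fit as chosen. For the Tfap2c knockdown it was called for 7 genes with a pseudocount of 0.1, 14 with 5, 55 with no filter, 51 with a filter of 5 FPKM, 11 after median-ratio rescaling and 11 after quantile normalization. For the Tead4 knockdown it was called for 32 with no filter. For the double knockdown it was called for 20 with a pseudocount of 5, 26 with no filter, 7 after median-ratio rescaling and 15 after quantile normalization. The cause was not tested.

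Leaving out 1 library gave 2608 to 3158 genes for the Tfap2c, 407 to 594 for the Tead4 and 2268 to 2695 for the double knockdown. The lowest Tead4 counts were 407 without GFP B2 and 446 without Tead4 knockdown B1. The double against Tead4 gave 2105 to 2531. The double against Tfap2c gave 8, 1, 5 and 6 without Tfap2c knockdown A1, A2, B1 and B2, and 8, 1, 6 and 10 without double knockdown A1, A2, B1 and B2. The non-additive part gave 51, 21 and 12 without GFP A1, A2 and B2, 50, 15, 13 and 17 without Tfap2c knockdown A1, A2, B1 and B2, 21, 23, 13 and 53 without Tead4 knockdown A1, A2, B1 and B2, and 17 and 55 without double knockdown A1 and B1. Without double knockdown A2 it was 113. The overlap ran from 138 to 251, with 170 without GFP A1, 138 without GFP B2 and 170 without Tead4 knockdown B1, and the correlation of the single knockdowns from 0.202 to 0.315. Passing lists numbered 4 to 5, 5 to 8 and 5 to 7. Each target's log2 change stayed between -1.21 and -1.02 or between -1.18 and -0.98 for Tfap2c, and between -2.72 and -2.43 or between -2.53 and -2.09 for Tead4, in the single and the double knockdown. In fits of 1 cross each group holds 2 libraries and the spread is pooled over groups.

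A replicate block on the labels A1, A2, B1 and B2 gave 8 genes for the double against the Tfap2c knockdown and 36 for the non-additive part. The labels do not say that equal labels share embryos, and residuals of 7 of 16 libraries correlated best with a library of their own label, so no pairing was used. Depth cannot be stated in reads, so the counting error of a low value is unknown. Relative depth differed by 1.28 times between the extremes of the 16 libraries. The log2 changes of genes near 1 FPKM depend on the pseudocount.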

Other observations

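No test in this part was chosen only after a result was seen, apart from the choice of the genes and libraries named.

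The single knockdowns moved some genes in opposite directions, and the genes here were chosen after their values were seen. Akr1b8 rose by 1.42 in the Tfap2c knockdown and fell by 2.70 in the Tead4 knockdown. Abcb1a rose by 0.97 and fell by 3.34 in the same order. Zfp352 had means of 0.761 and 8.06 FPKM in crosses A and B of the control, and 3.36 and 24.2 FPKM in crosses A and B of the double knockdown.

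In 6 pairs of named gene and comparison, the libraries of 1 cross all lay above their controls and those of the other cross all below theirs. Pairs whose means differed in sign while libraries overlapped are not counted. The 6 pairs were Yap1 and Anxa2 in the Tfap2c knockdown, and Tfap2c, Pard6b, Oasl2 and Uchl1 in the Tead4 knockdown. By limma's interaction test 0 genes passed for either knockdown (1888 and 797 at an unadjusted p under 0.05). Under alternatives the count reached 55 for the Tfap2c and 32 for the Tead4 knockdown, both with no filter. The transcript Gm24336 was listed at 0 in some libraries and above 80 FPKM in others, with 216, 122, 216 and 216 FPKM in the Tfap2c knockdown, 110 FPKM in Tead4 knockdown A1 and 83.4 FPKM in double knockdown B1.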
